A study of Mus musculus with 12 samples.

How the data were processed

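RNA was measured in 12 libraries of sorted mouse CD8 T cells, 3 in each of 4 arms: isotype control, anti-CTLA-4, anti-PD-1 DANA and the combination. Per the labels' protocols, cells of 5 mice per arm were pooled and split in triplicate, 0.25 ng of RNA was amplified with 21 cycles in a Smart-seq2-type protocol, Nextera adapters were added, and libraries were sequenced on an Illumina HiSeq instrument. Antibodies were given on days 3, 6 and 9 per the sample labels, and on days 3, 6 and 8 per the series text. Harvest was on day 28, counted from treatment in the sample labels and from tumour injection in the series text. The labels state about 48710 reads per library, a number equal to the lines of each table and far below the recovered depth, so it was not used as a depth.

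Reads were aligned and quantified in CLC Genomics Workbench, per the labels' protocols, against GRCm38.p5, per the submitters' processing notes. The version of that program, the annotation release and the statistical model are not given in the sources used here. The authors deposited 1 table per treatment against isotype, each with a gene's chromosome and region, the larger of the 2 group means, a log2 fold change, a signed fold change, a p-value, a false discovery rate and a Bonferroni p-value. The larger group mean in the authors' table is in RPKM. Its unit was read from the values: where all treatments are lower, the 3 tables hold the same mean, and low means are sums of whole reads. The log2 fold change and the signed fold change deposited by the authors are positive where the treated group is higher. The p-values in the authors' tables were corrected over all 48709 listed genes, although 17833 were tested and 30876 were not. Of the untested genes 2608 had a mean above 0.

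The tables hold comparisons and no value per library, so the fallback fixed before the data were examined was used: the authors' tables as deposited, with an adjusted p (their Benjamini-Hochberg false discovery rate) under 0.05 as a call. The planned count models on all libraries could not be fitted, nor their alternatives (other normalizations and tests, count filters, fits with only the compared groups, replicate and sample-sheet blocks, leaving out a library, the rotation list test, estimated inter-gene correlation, and segment shares per library). How many libraries show a change's direction can therefore not be given. Gene names and coordinates are the files' own, and 48349 genes (99.3%) matched GENCODE mouse release M21, which gave exon lengths; 88.4% of these had the same coordinates there.

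Every step from here to the end of the paragraph was chosen after the data had been seen. A standard error was implied as the absolute log2 fold change over the normal quantile of the p-value, which assumes a Wald test. The combination against each antibody, and its departure from additivity, were computed from differences of fold changes. For the 10235 genes (57.4%) whose 3 standard errors lie within 5% of each other, equal variances of the group means set the error of the difference. For the others an upper bound was used, and this rule was set after the bound alone had been seen to leave few calls. Benjamini-Hochberg adjustment again covered all listed genes. Library sizes were recovered from the steps of low RPKM means, which are sums of whole reads over library size and exon length. They ranged from 14729713 to 42556869 reads over 12 libraries and cannot be tied to replicate numbers. Whole reads per library were then solved for genes with few reads where chance allowed at most 0.05 solutions. This solved 78.6 to 82.2% of the means tried, against 2.22 to 4.16% with exon lengths off by 1 base. A gene was said to rest on 1 library where that library gave 80% or more of the larger mean. The scaling used by the authors was compared with library size through genes whose group means are both known, with an isotype mean of 5 RPKM or more. This used 530, 354 and 236 genes for anti-CTLA-4, anti-PD-1 DANA and the combination.

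In all 26 gene lists with 3 or more tested members, written before the data were examined, were tested with limma's cameraPR on signed z scores. The test is two-sided with an inter-gene correlation of 0.01, and p-values were adjusted over the lists. Alternatives were a correlation of 0.05, ranks, library size scaling, and z scores centred in 20 bins of expression level. The correlation camera would estimate cannot be had from tables without values per library. Medians were set beside those of 10000 random lists matched on level. Counts of called members are given over all genes and adjusted over the list alone. Alternatives for counts of genes were adjustment over tested genes, Bonferroni adjustment, a larger mean of 5 RPKM or more, library size scaling, the upper bound of the error, and removal of genes resting on 1 library. All of these alternatives were chosen after the data had been seen. Shared controls were simulated with 100 draws of unchanged groups.

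Genes to be named were fixed by a rule before the data were examined: Pdcd1, Ctla4, Ifng, Ifngr1, Ifngr2, Fas, Fasl and Bcl2, the 8 highest and 8 lowest called fold changes above the median level, and up to 2 called members of each list per direction. Predicted loci and receptor segments were left out of the fold part. Not every gene picked by the rule is named. A condition of that rule on the order of single libraries could not be applied. Other genes were chosen after their values were seen: Gzmb, Gzmk, Gzmm, Il18rap, Bbc3, Bank1, Ets1, Slamf6, Isg15, Ifih1, Ms4a1, Pou2af1 and Ly6d where outside the rule, the mitochondrial genes other than mt-Atp8 and mt-Nd5, the receptor segments, Lars2, Rn18s-rs5 and Malat1.

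The steps were tested on simulated data. Recovery of library sizes was exact for all 3 libraries in 9 of 10 simulated groups of 17000 genes, and an earlier test with sizes near whole multiples of each other failed. Of simulated genes 99.9% were solved, all of these with the true reads, against 2.16% with lengths off by 1 base. For the combination against anti-CTLA-4, with 200 of 17833 genes changed, 1.38, 10.6 and 63.8% were recovered at log2 changes of 2, 4 and 8, with 2.67, 5.38 and 5.42% false among the calls. With the upper bound 0.075, 2.40 and 28.9% were recovered. This simulation adjusted over its 17833 genes alone, which is less strict than the adjustment over all listed genes used for the reported contrasts. It drew all groups with equal variances, so its false shares do not test the assumption of equal variances. Recovery and false shares under the mixed rule for the error used in the reported contrasts were not simulated. A list shifted by 1 z unit was called in 100% of 100 draws and other lists in 0.0476%. These draws had independent genes, so the 0.0476% does not give the rate of false list calls where genes vary together. The median implied standard error of tested genes was 1.95, 1.93 and 1.94 for the 3 comparisons against isotype, so that changes under several log2 units were not detectable for most genes. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.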

Results

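The series measured RNA in CD8 T cells specific for a tumour antigen after checkpoint blockade in C57BL/6 mice. TRAMP-C2, a transplantable line from a mouse prostate tumour, was injected, and live CD45+CD3+CD8+ cells that bound the Spas-1 tetramer but not the Spas-2 tetramer were sorted from draining lymph nodes. The 4 arms received an isotype control antibody, anti-CTLA-4, anti-PD-1 DANA, or the combination of anti-CTLA-4 with anti-PD-1 DANA. DANA names an Fc mutation that removes binding to Fc receptors. Cells from 5 mice were pooled per arm and each pool was divided into 3 libraries, 12 in all, so the libraries of an arm are technical splits of 1 pool and every p-value measures only the spread between such splits. Arm and pool cannot be told apart. Recovered depths ranged from 14729713 to 29583827 reads per library for anti-CTLA-4, from 24233466 to 31943900 for anti-PD-1 DANA, from 24594651 to 42556869 for the combination and from 23973359 to 32867235 for isotype. The series title concerns deletion of tumour-specific T cells by interferon-gamma and resistance to combined checkpoint blockade, and the 3 comparisons against isotype, with their contrasts, bear on how the RNA of the sorted pools differed between arms. Some B cell markers were abundant in the isotype arm too, with Cd74 at 156.8, Igkc at 90.2 and H2-Eb1 at 77.8 RPKM. A change in a marker of another cell type may therefore not lie in the CD8 T cells.

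The authors' deposited table of each comparison against isotype lists 48709 genes, of which 17833 were tested. Fold changes are log2 values from these tables, ± the standard error implied by the authors' p-value. For genes scarce in 1 arm a fold change depends on the authors' fit, and the lower arm's mean cannot be read from the tables. Values of this kind are therefore given as log2 only. The authors' scaling placed the median tested gene at a log2 fold change of -0.62 for anti-CTLA-4, -0.45 for anti-PD-1 DANA and -0.42 for the combination, and list tests compare a list with all other tested genes. Scaling by library size would raise fold changes by 0.95, 0.82 and 0.11 respectively.

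**Figure D1:**
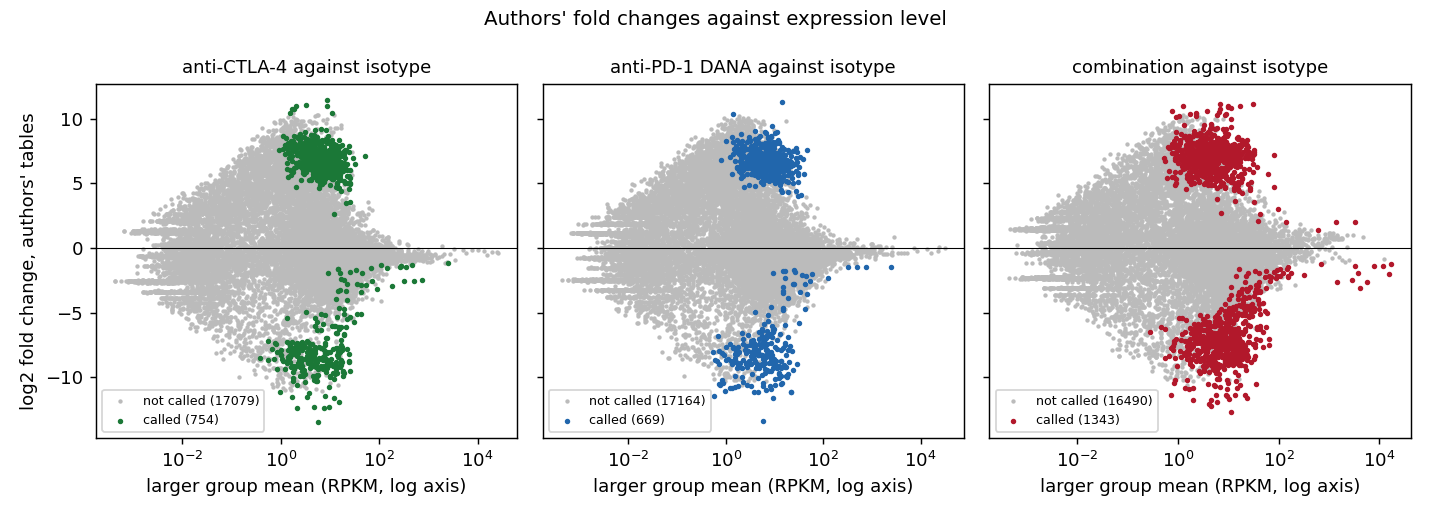
Each point is 1 of 17833 tested genes, with the larger of the treated and isotype group means on the horizontal log axis (RPKM) and the authors' log2 fold change on the vertical axis, for each treatment against isotype. Coloured points have an adjusted p under 0.05, and most called genes lie far from 0 at a few RPKM, where the median larger mean of called genes was 6.03, 6.57 and 6.04 RPKM.

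Anti-CTLA-4 against isotype asked what CTLA-4 blockade alone changed. Of effector and cytotoxic genes, which did not pass as a list (adjusted p = 0.864), 2 of 35 were called higher. Prf1, which encodes the pore-forming protein perforin, had a log2 fold change of 5.57 ± 1.33 (adjusted p = 0.00774) and Tbx21, the transcription factor T-bet, 7.27 ± 1.52 (adjusted p = 0.00204) in the authors' deposited table. Of 25 inhibitory receptors and exhaustion factors 2 were called lower, Lag3, a receptor for MHC class II, at -8.20 ± 1.46 (adjusted p = 0.000165) and Cd200r1, the receptor for CD200, at -9.02 ± 1.99 (adjusted p = 0.00375) in the authors' deposited table. Interferon-stimulated genes were lower as a list (adjusted p = 0.00346, or 0.117 with an inter-gene correlation of 0.05). Klf2, a transcription factor of quiescent and recirculating T cells, fell by 3.14 ± 0.69 (adjusted p = 0.00344) in the authors' deposited table. Of 23 B cell markers 5 were called higher in the same libraries, led by Spib, a transcription factor of B cells and plasmacytoid dendritic cells, at 7.89 ± 1.66 (adjusted p = 0.00212) in the authors' deposited table. By the authors' deposited table, 754 genes passed an adjusted p of 0.05, 488 higher and 266 lower, with a median absolute log2 fold change of 7.20. Of 36 called with a standard error under 1, 3 were higher and 33 lower, where the authors' scaling centres genes of 20 to 100 RPKM at -1.11, against -0.16 by library size. Of 27 past Bonferroni adjustment 11 were higher and 16 lower. In GRCm38 coordinates of the authors' deposited table, Prf1 lies on chromosome 10 at 61297836 to 61304263, Tbx21 on chromosome 11 at 97098071 to 97115331, Lag3 on chromosome 6 at 124904361 to 124911705 and Spib on chromosome 7 at 44525993 to 44532071.

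Among 26 lists fixed before the data were examined, 10 passed a competitive list test after anti-CTLA-4. B cell markers were higher (adjusted p = 0.00346), with 5 of 23 members called higher and none lower over all genes in the authors' deposited table, and 7 higher when adjusted over the list alone. The called members were Spib, Fcer2a (the low-affinity IgE receptor CD23), Ms4a1 (CD20), Pou2af1 (a coactivator of B cell transcription) and Ly6d, of which Fcer2a stood at 7.53 ± 1.68 (adjusted p = 0.00417) in the authors' deposited table. Inhibitory receptors and exhaustion factors were lower (adjusted p = 0.0186), with Lag3 and Cd200r1 the 2 called of 25 members, and 1 higher and 3 lower when adjusted over the list alone. Interferon-stimulated genes were lower (adjusted p = 0.00346), with 2 of 56 members called lower and 1 higher and 6 lower when adjusted over the list alone. Ifit3, an interferon-induced antiviral gene, stood at -6.13 ± 1.81 (adjusted p = 0.0479) in the authors' deposited table. Naive and memory genes were lower (adjusted p = 0.00339), with Klf2 the only called member of 25 and 2 lower when adjusted over the list alone. Genes of the T cell receptor complex and its proximal signalling were lower (adjusted p = 0.00424), with 2 of 30 called and 3 lower when adjusted over the list alone. Lat, the adaptor that nucleates T cell receptor signalling, stood at -1.45 ± 0.39 (adjusted p = 0.0246) and Ptprc, which encodes CD45, at -1.33 ± 0.36 (adjusted p = 0.0254) in the authors' deposited table. On the scale of library size these were -0.51 and -0.38 and not called, and Ifit3, at -5.18 there, was not called either.

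The other 5 lists called after anti-CTLA-4 had few called members. Nuclear oxidative phosphorylation genes were lower (adjusted p = 0.00774) with 0 of 41 members called, and mitochondrially encoded genes were lower (adjusted p = 0.0451) with 0 of 13 called. Immediate early and dissociation stress genes were lower (adjusted p = 0.0223), although Rgs1, a regulator of G protein signalling, rose by 8.14 ± 1.72 (adjusted p = 0.00218) while Hspa1a, an inducible heat shock protein, fell by 8.31 ± 1.65 (adjusted p = 0.00141) in the authors' deposited table. Targets of p53 were higher (adjusted p = 0.0451), with Gadd45b, a stress and growth arrest gene, the called member of 19 and 7 higher and 1 lower when adjusted over the list alone. Erythroid and platelet markers were higher (adjusted p = 0.0246) with 0 of 4 called and 3 higher when adjusted over the list alone. With an inter-gene correlation of 0.05 none of the 10 lists passed, with adjusted p = 0.0867 for B cell markers, 0.119 for inhibitory receptors and 0.117 for interferon-stimulated genes. After removal of the trend with expression level, B cell markers (adjusted p = 0.000185) and inhibitory receptors (adjusted p = 0.0387) passed, and on library size scaling these same 2 lists passed. Among random lists matched on level the median of B cell markers lay at percentile 99.9, of interferon-stimulated genes at 0.68 and of inhibitory receptors at 2.25. Medians of the naive and memory (percentile 48.5), immediate early (61.4), oxidative phosphorylation (62.2) and T cell receptor lists (92.7) were not low for genes of their level. The mitochondrially encoded list lay at percentile 98.1. Its genes are far more abundant than most genes of the top level bin, so that percentile does not compare them with genes of their level. The 16 lists not called had adjusted p from 0.0618 to 0.997. They include the interferon-gamma pathway components (adjusted p = 0.0618) and effector genes (adjusted p = 0.864), whose median was -0.24 although the test pointed up.

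Called members of other uncalled lists went both ways after anti-CTLA-4. The death genes Casp6, an executioner caspase, rose by 7.34 ± 1.94 (adjusted p = 0.0202), while Htra2, a mitochondrial protease that counters caspase inhibitors, fell by 6.65 ± 1.65 (adjusted p = 0.011) in the authors' deposited table. Birc6, an inhibitor of apoptosis, fell by 1.90 ± 0.46 (adjusted p = 0.0081) in the authors' deposited table, a call lost on library size scaling (-0.95), as was that of Fcgr3 (-10.28 there). Of proliferation genes, Bub1b, a spindle checkpoint kinase, was at 8.43, E2f2, a cell cycle transcription factor, at -7.50 and Tyms, thymidylate synthase, at -8.05 in the authors' deposited table (adjusted p = 0.0496, 0.00236 and 0.0228). Il15ra, the receptor chain that binds interleukin-15, was called higher at 6.85, and Dnajb9, a chaperone of the endoplasmic reticulum, at 7.20 in the authors' deposited table. Ldhb, a lactate dehydrogenase subunit, was called lower at -8.02 in the authors' deposited table. Of myeloid markers, C1qa (complement), Mpeg1 (macrophage perforin-2) and Fcgr3 (an Fc receptor) were called lower at -9.69, -9.18 and -11.23 in the authors' deposited table, and the CD4 co-receptor gene Cd4 was called higher at 8.23.

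Large called changes after anti-CTLA-4 among genes above the median level were upward in Coq8a (11.06), a coenzyme Q synthesis gene, Mid1ip1 (11.03), Pakap (10.97), Ocrl (10.81), an inositol phosphatase, Mthfs (10.74), a folate enzyme, Rpa3 (10.48), a replication protein A subunit, and Heatr5a (10.42) in the authors' deposited table. Downward they were Myo1h (-13.48), a myosin, Timd4 (-12.36), a phosphatidylserine receptor, Ggnbp1 (-12.35), Fbxl15 (-12.28), Ccl7 (-11.62), a monocyte chemokine, Ttc39c (-11.55), Fcgr3 (-11.23) and Plxnb1 (-10.62), a semaphorin receptor, in the authors' deposited table. Their standard errors, implied by the authors' deposited table, ranged from 2.40 (Plxnb1) to 3.36 (Fbxl15). Reads of 80% or more from 1 library made up the larger mean of Timd4, Fbxl15, Ccl7, Fcgr3, Ifit3, Ldhb and C1qa in isotype and of Coq8a, Mid1ip1, Bub1b and the uncalled Fasl in anti-CTLA-4. Of the 8 genes named in advance none was called: Fasl, the Fas ligand, was at 8.31 ± 2.58 (adjusted p = 0.0661), Bcl2 at -1.43 ± 0.48 (adjusted p = 0.111), Ifngr1 at 1.75 ± 0.89 (adjusted p = 0.586), and Pdcd1, Ctla4, Ifng, Ifngr2 and Fas at -1.38, -2.19, -1.91, -2.87 and 0.93 (adjusted p = 1 each) in the authors' deposited table. With scaling by library size 1367 genes passed, 1188 higher and 179 lower, against 64.7% higher on the authors' scaling and 86.9% on this one. Where whole reads could be recovered, 102 of 114 genes called lower (89.5%) rested on 1 of the isotype libraries, against 76.9% of uncalled genes of the same level, while 29 of 251 called higher (11.6%) rested on 1 anti-CTLA-4 library, against 26.3%. Leaving out the genes found to rest on 1 library left 623, most of which could not be assessed for it.

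Anti-PD-1 DANA against isotype asked the same of PD-1 blockade. Of effector and cytotoxic genes, which did not pass as a list (adjusted p = 0.114), 4 of 35 were called higher. Prf1 had a log2 fold change of 7.07 ± 1.33 (adjusted p = 0.000363), Tbx21 6.65 ± 1.52 (adjusted p = 0.00559), and the granzyme genes Gzmb and Gzmk, proteases that enter target cells through perforin pores, 7.82 ± 2.28 (adjusted p = 0.0449) and 7.58 ± 2.01 (adjusted p = 0.0212) in the authors' deposited table. Gzmb and Gzmk were named after their values were seen. Tnfrsf4, the costimulatory receptor OX40, rose the most of the named genes, by 11.28 ± 3.04 (adjusted p = 0.0248) in the authors' deposited table. Dusp2, a phosphatase induced by activation, fell by 2.35 ± 0.58 (adjusted p = 0.0125) in the authors' deposited table, a call lost on library size scaling (-1.54). The authors' deposited table held 669 genes past an adjusted p of 0.05, 434 higher and 235 lower, with a median absolute log2 fold change of 7.07. Of 26 called with a standard error under 1, 2 were higher and 24 lower, where genes of 20 to 100 RPKM centre at -1.02, against -0.21 by library size. Of 34 past Bonferroni adjustment 15 were higher and 19 lower. Tnfrsf4 lies on chromosome 4 at 156013843 to 156016612.

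After anti-PD-1 DANA 3 of the 26 lists passed. Naive and memory genes were lower (adjusted p = 0.00389) with 0 of 25 members called and 1 lower when adjusted over the list alone. The T cell receptor list was lower (adjusted p = 0.0177) with 0 of 30 called and 1 lower when adjusted over the list alone. Immediate early and dissociation stress genes were lower (adjusted p = 0.00389), with 1 of 29 called higher and 2 lower, and 1 higher and 4 lower when adjusted over the list alone. Rgs1 stood at 7.37 ± 1.72 (adjusted p = 0.00667), Dusp2 at -2.35 ± 0.58 and the heat shock gene Hsph1 at -2.75 ± 0.78 (adjusted p = 0.037) in the authors' deposited table. With an inter-gene correlation of 0.05 none of these passed, with adjusted p = 0.101, 0.173 and 0.101, and none passed after removal of the expression level trend or on library size scaling. Their medians lay at percentile 52.7, 72.9 and 4.60 of random lists matched on level, so the first 2 were not low for genes of their level. Effector and cytotoxic genes missed the threshold (adjusted p = 0.114) although 4 of 35 members were called higher and 11 were higher when adjusted over the list alone, and they passed with the level trend removed (adjusted p = 0.0111) and on library size scaling (adjusted p = 0.0462) but not with ranks (adjusted p = 0.43) or a correlation of 0.05 (adjusted p = 0.416). The mitochondrially encoded list, not called here (adjusted p = 0.519), was higher on library size scaling (adjusted p = 0.0462). Adjusted p of the 23 uncalled lists ran from 0.0687 to 0.981, and they include the interferon-gamma pathway components (0.0687), interferon-stimulated genes (0.0708) and B cell markers (0.69).

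Within uncalled lists, Cd86, a shared ligand of CTLA-4 and CD28, rose by 7.07 ± 1.91 (adjusted p = 0.0248), Casp6 by 7.07 ± 1.94 (adjusted p = 0.0275) and Gadd45b by 6.70 ± 1.78 (adjusted p = 0.0212) in the authors' deposited table. Rrm1, a ribonucleotide reductase subunit, and Stmn1, a microtubule regulator, were called higher at 6.89 and 7.36, and E2f2 lower at -8.33, in the authors' deposited table. Birc6 fell by 1.80 ± 0.46 (adjusted p = 0.0146) and the interferon-induced gene Ifi44 fell by 8.65 ± 2.42 (adjusted p = 0.0324) in the authors' deposited table. Of markers of other cells, Csf1r, the macrophage growth factor receptor, was called higher at 8.44, while Fcgr3 (-11.14), the B cell adaptor gene Blnk (-7.35), the chemokine receptor gene Ccr6 (-5.78) and the integrin gene Itga2 (-9.27) were called lower in the authors' deposited table.

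Among called genes above the median level, with receptor segments and predicted loci left out, the largest upward after anti-PD-1 DANA were Tnfrsf4 (11.28), Slc35f2 (9.48), Fgl2 (9.09), Hibch (9.02), a valine catabolism enzyme, Cbll1 (9.00), Pradc1 (8.92), Tnfaip8l1 (8.91) and Pex14 (8.81), a peroxisomal import protein, in the authors' deposited table. Downward they were Myo1h (-13.39), Fcgr3 (-11.14), Pklr (-10.74), a pyruvate kinase, Rps6ka5 (-10.70), Dnhd1 (-10.70), Prrt2 (-10.66), Slc6a12 (-10.59), a betaine and GABA transporter, and Zglp1 (-10.56) in the authors' deposited table. Fcgr3, Pklr, Prrt2 and Ifi44 rested on 1 isotype library and Fgl2 and the uncalled Fasl and Ctla4 on 1 anti-PD-1 DANA library for 80% or more of their reads. None of the 8 genes named in advance was called: Bcl2 was at -1.57 ± 0.48 (adjusted p = 0.0671), Fasl at 6.78 ± 2.59 (adjusted p = 0.196), and Pdcd1, Ctla4, Ifng, Ifngr1, Ifngr2 and Fas at -1.47, -0.31, -2.56, 0.94, -2.41 and 0.32 (adjusted p = 1 each) in the authors' deposited table. On library size scaling 1221 genes passed, 1055 higher and 166 lower, or 86.4% higher against 64.9%, and Pklr, Birc6, Dusp2, Hsph1 and Ccr6 did not. Of genes called lower with recovered reads, 91 of 98 (92.9%) rested on 1 isotype library, against 77.8% of uncalled genes of the same level, while 17 of 155 called higher rested on 1 anti-PD-1 DANA library, a smaller share than the 26.6% of uncalled genes. With the genes found to rest on 1 library left out 561 remained, most of them not assessed.

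The combination against isotype asked what the antibodies did together. Of 13 transcripts of the mitochondrial genome 10 were called lower: mt-Atp8, an ATP synthase subunit, had a log2 fold change of -3.13 ± 0.38 (adjusted p = 5.41e-12), mt-Nd5, a complex I subunit, -2.66 ± 0.33 (adjusted p = 2.70e-11) and mt-Cytb, the cytochrome b of complex III, -2.61 ± 0.33 (adjusted p = 3.97e-11) in the authors' deposited table. Of interferon response genes, Irf1, a transcription factor induced by interferon-gamma, was called lower at -2.22 ± 0.55 (adjusted p = 0.00664) and the immunity GTPase gene Irgm1 at -4.93 ± 0.94 (adjusted p = 0.00024) in the authors' deposited table. Il2rg, the shared cytokine receptor chain, fell by 2.12 ± 0.41 (adjusted p = 0.000306) in the authors' deposited table. Prf1 (5.34 ± 1.33, adjusted p = 0.00695), Tbx21 (6.97 ± 1.52, adjusted p = 0.00162) and Gzmm (6.77 ± 1.96, adjusted p = 0.0265), another granzyme gene, were called higher in the authors' deposited table. For Tbx21 95.5% of the recovered combination mean lay in 1 library. The authors' deposited table held 1343 genes past an adjusted p of 0.05, 703 higher and 640 lower, with a median absolute log2 fold change of 7.17. Of 70 called with a standard error under 1, 10 were higher and 60 lower, where genes of 20 to 100 RPKM centre at -0.89, against -0.79 by library size. Of 74 past Bonferroni adjustment 28 were higher and 46 lower. Irf1 lies on chromosome 11 at 53770014 to 53778374 and Irgm1 on the same chromosome at 48861968 to 48871683.

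With the combination 4 of the 26 lists passed. Mitochondrially encoded genes were lower (adjusted p = 9.98e-22), with 10 of 13 members called lower, 12 lower when adjusted over the list alone, and a median of -1.38. The members not called were mt-Co3 (-0.83, adjusted p = 0.208), mt-Nd6 (-1.05, adjusted p = 0.0953) and mt-Nd3 (0.74, adjusted p = 0.642) in the authors' deposited table, and some of these genes overlap or adjoin on the mitochondrial genome, so their reads could be shared. mt-Atp8 lies at 7766 to 7969 and mt-Cytb at 14145 to 15288 of chromosome MT in GRCm38. This list also passed with a correlation of 0.05 (adjusted p = 2.85e-15), on library size scaling (adjusted p = 1.23e-19) and with the level trend removed (adjusted p = 1.04e-19). With ranks its adjusted p was 1.77e-05. In each of these tests the inter-gene correlation was set and not estimated. If the 13 genes vary together more than that, their list p-values are too small, here and in the contrasts below. Interferon-stimulated genes were lower (adjusted p = 0.00577), with 1 of 56 called higher and 6 lower, and 2 higher and 16 lower when adjusted over the list alone. Tap1, the peptide transporter of antigen presentation, fell by 2.26 ± 0.52 (adjusted p = 0.00278) while Psmb9, an immunoproteasome subunit, rose by 2.65 ± 0.81 (adjusted p = 0.0404) in the authors' deposited table, and Ifit3, Ifih1 and Isg15 were also called lower. Naive and memory genes were lower (adjusted p = 0.00577), with 4 of 25 called lower, among them Slamf6, Il6ra and Ets1, and 5 lower when adjusted over the list alone. Il6ra, the interleukin-6 receptor, stood at -3.16 ± 0.78 (adjusted p = 0.00629) in the authors' deposited table. The T cell receptor list was lower (adjusted p = 0.0177), with 2 of 30 members called lower over all genes and over the list alone. Ptpn6, the phosphatase SHP-1, was at -1.65 ± 0.46 and the adaptor gene Sh2d2a at -1.93 ± 0.53 in the authors' deposited table (adjusted p = 0.0211 and 0.0184). These last 3 lists did not pass with a correlation of 0.05 (adjusted p = 0.154, 0.131 and 0.154) or with the level trend removed (adjusted p = 0.109, 0.152 and 0.289), and on library size scaling the T cell receptor list did not pass (adjusted p = 0.0533). Among random lists matched on level the medians lay at percentile 0.80 for mitochondrially encoded genes, 0.36 for interferon-stimulated genes, 28.9 for naive and memory genes and 50.7 for the T cell receptor list. For mitochondrially encoded genes the match on level is poor, as most genes of the top level bin are far scarcer.

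**Figure D2:**
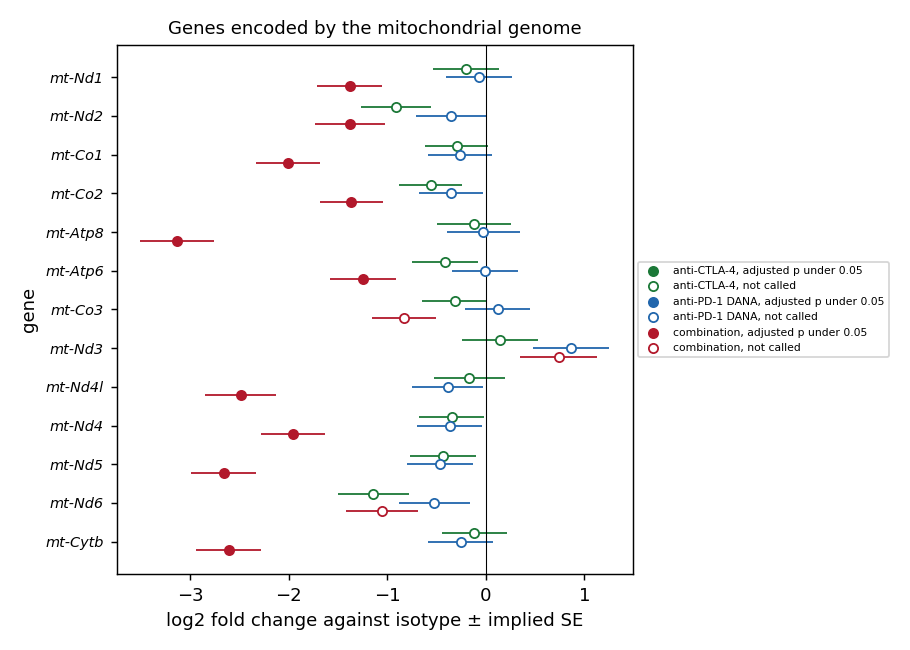
Log2 fold change against isotype (horizontal axis) of the 13 genes encoded by the mitochondrial genome (vertical axis), with 1 point per treatment from the authors' tables and bars of ± 1 implied standard error; filled points have an adjusted p under 0.05. With the combination 10 of 13 genes were called lower, down to -3.13 for mt-Atp8, while mt-Nd3 lay at 0.74 and no gene was called with either antibody alone on the authors' scaling; on library size scaling the list was higher after anti-PD-1 DANA.

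Effector and cytotoxic genes missed the threshold with the combination (adjusted p = 0.0958) although 6 of 35 members were called higher, Prf1, Tbx21, Gzmk, Gzmm, Il18rap and Il12rb2, and 10 were higher and 1 lower when adjusted over the list alone. The list passed with the level trend removed (adjusted p = 0.0232) but not on library size scaling (adjusted p = 0.0759), with ranks (adjusted p = 0.423) or with a correlation of 0.05 (adjusted p = 0.352). Il12rb2, a chain of the interleukin-12 receptor, stood at 8.58 ± 2.23 (adjusted p = 0.0102), Il18rap, a chain of the interleukin-18 receptor, at 5.04 ± 1.39 (adjusted p = 0.0178) and Gzmk at 6.60 ± 2.01 (adjusted p = 0.0414) in the authors' deposited table, and Gzmk, Gzmm and Il18rap were named after their values were seen. The pro-apoptotic BCL2 family was not called (adjusted p = 0.312), but 3 of 11 members were called higher: Bad (6.68 ± 1.82), Bmf (8.32 ± 2.41) and Bbc3, the p53 target PUMA (7.24), in the authors' deposited table. The caspase genes Casp1 and Casp6 were called higher at 8.52 and 7.11, and Dffb, the nuclease that cuts DNA in apoptosis, and Tradd, an adaptor of death receptors, lower at -7.67 and -4.97 in the authors' deposited table, in a list that was not called (adjusted p = 0.726). Birc6 fell by 1.61 ± 0.46 (adjusted p = 0.0222), and the DNA damage genes Gadd45b and Rrm2b were called higher at 6.91 each in the authors' deposited table. Mki67, which encodes the proliferation antigen Ki-67, was called higher at 9.54 ± 2.30 (adjusted p = 0.00483) and Birc5, the mitotic protein survivin, at 5.90 ± 1.81 (adjusted p = 0.0435) in the authors' deposited table. The costimulatory receptor gene Tnfrsf9 (-7.42), Cd200r1 (-8.77), Ldhb (-7.77), Fosb (-7.82), Dusp2 (-1.95) and the unfolded protein response genes Xbp1 (-5.13) and Creld2 (-6.01) were called lower in the authors' deposited table. Adjusted p of the 22 uncalled lists ran from 0.0603, for the interferon-gamma pathway components with Irf1 called of 10, to 0.963.

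Markers of other cells moved both ways with the combination. B cell markers were not called as a list (adjusted p = 0.63), with 2 of 23 members higher and 3 lower. Ly6d (6.32) and Fcer2a (5.44) were called higher and Blnk (-8.06), Cd22 (-6.38) and Bank1 (-5.28) lower in the authors' deposited table. Of myeloid markers Lyz2, lysozyme, was called lower at -4.26 and Fcgr3 at -7.63, and the chemokine receptor genes Ccr6 (-8.55) and Ccr8 (-7.77) and the integrin gene Itga2 (-9.59) were called lower in the authors' deposited table. Cd163l1, a gene of gamma-delta T cells, was called higher at 6.70 in the authors' deposited table.

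**Figure D3:**
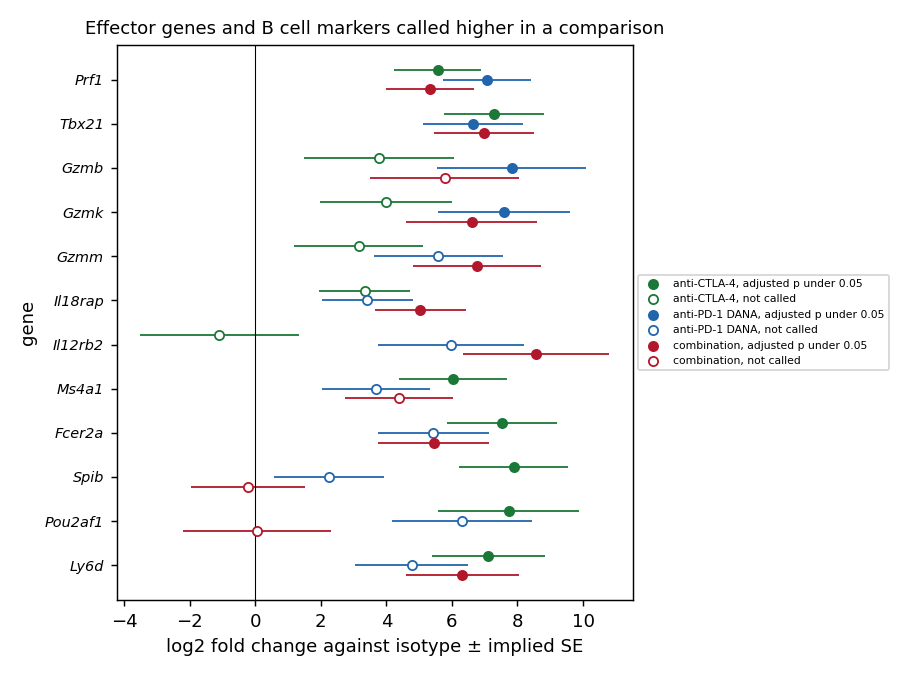
Log2 fold change against isotype (horizontal axis) of 7 effector genes and 5 B cell markers (vertical axis) called higher in a comparison, with 1 point per treatment from the authors' tables and bars of ± 1 implied standard error; filled points have an adjusted p under 0.05. Prf1 and Tbx21 are filled for all 3 treatments, while Spib lies at 7.89 with anti-CTLA-4 and at -0.22 with the combination.

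Among called genes above the median level, with receptor segments and predicted loci left out, the largest upward with the combination were Hopxos (11.16), an RNA antisense to Hopx, Mthfs (10.98), Neurl2 (10.95), the histone gene Hist1h4j (10.85), Fam166a (10.56), Wnt3 (10.43), Nlrc4 (10.37), an inflammasome gene, and Mfsd12 (10.33) in the authors' deposited table. Downward they were Trim34b (-12.70), Lrrc29 (-12.22), Vti1a (-12.07), a SNARE protein, Apol7b (-11.88), Amigo1 (-11.79), Amigo3 (-11.78), Atp5s (-11.40) and the olfactory receptor gene Olfr262 (-11.36) in the authors' deposited table. Smart-seq2-type libraries do not mark strand, so reads of Hopxos and its sense partner cannot be told apart. At least 80% of recovered reads came from 1 library for Tbx21, Gzmk, Casp1, Bmf, Bbc3, Ly6d, Cd163l1, Hopxos, Neurl2, Hist1h4j and Wnt3 in the combination, and for Trim34b, Lrrc29, Amigo1, Olfr262, Tnfrsf9, Ldhb, Ifit3, Fcgr3 and the uncalled Fasl in isotype. None of the 8 genes named in advance was called: Bcl2 was at -1.33 ± 0.48 (adjusted p = 0.132), Ifngr1 at 1.77 ± 0.89 (adjusted p = 0.549), Ifngr2 at -3.23 ± 1.87 (adjusted p = 0.845), and Pdcd1, Ctla4, Ifng, Fas and Fasl at -0.79, -0.36, -0.42, 1.02 and -0.55 (adjusted p = 1 each) in the authors' deposited table. On library size scaling 1359 genes passed, and Dusp2 (-1.84 there) and Ccr8 (-7.66) did not, although their fold changes moved little. Of genes called lower with recovered reads, 196 of 232 (84.5%) rested on 1 isotype library, against 68.9% of uncalled genes of the same level, 176 of 271 genes called higher (64.9%) rested on 1 combination library, against 57.0%. Of the 971 called genes left without these, most could not be assessed.

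The combination was set against anti-CTLA-4 alone by subtracting the authors' fold changes, which share the isotype libraries. Mitochondrial transcripts were lower in the combination, with mt-Atp8 at -3.01 ± 0.38 (adjusted p = 1.27e-11) and mt-Cytb at -2.49 ± 0.33 (adjusted p = 3.76e-10), and B cell markers were lower, led by Spib at -8.12 ± 1.70 (adjusted p = 0.0023). Lag3 was higher at 7.24 ± 1.44 (adjusted p = 0.000955), as were the proliferation genes Birc5 at 8.37 ± 1.86 (adjusted p = 0.00564) and E2f2 at 6.13 ± 1.58 (adjusted p = 0.0391). In this contrast 161 genes passed, 77 higher and 84 lower in the combination. Mitochondrially encoded genes (adjusted p = 2.61e-21) had 6 of 13 members called lower and 9 when adjusted over the list alone, with a median of -1.18. B cell markers (adjusted p = 2.10e-06) had 1 of 23 called lower and 6 when adjusted over the list alone, with a median of -1.49. Both lists also passed with a correlation of 0.05 (adjusted p = 5.60e-15 and 0.000843), with ranks (adjusted p = 0.000286 and 0.00012) and on library size scaling. CD4 and regulatory T cell markers were lower (adjusted p = 0.0391) with 0 of 12 called, and nuclear oxidative phosphorylation genes higher (adjusted p = 0.0307) with 0 of 41 called, and neither passed with the level trend removed (adjusted p = 0.0913 and 0.469) or with a correlation of 0.05 (adjusted p = 0.156 and 0.241). Neither passed on library size scaling (adjusted p = 0.0617 and 0.679), and the median of the oxidative phosphorylation list lay at percentile 83.3 of random lists matched on level. The 22 uncalled lists had adjusted p from 0.0785 to 0.97. Of these, the T cell receptor list was lower on library size scaling (adjusted p = 0.00404) but did not pass with the level trend removed (adjusted p = 0.505).

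Other genes higher in the combination than after anti-CTLA-4 were Myo1h (13.67), Lrrc47 (10.62), Gatb (8.91), Sp6 (8.84), Clcn5 (8.83), a chloride transporter, Tmem37 (8.74), Chaf1a (8.43), a chromatin assembly factor, and Hspa1a (7.40). Lower were Pskh1 (-7.89), Pramef8 (-7.87), Dhx32 (-7.70), Plbd2 (-7.65), Tmem9 (-7.63), Ccdc86 (-7.61), Ext2 (-7.52), a heparan sulfate polymerase, and Pfkl (-6.63), a phosphofructokinase of glycolysis. Among the 8 genes named in advance the differences were 0.60 for Pdcd1, 1.83 for Ctla4, 1.49 for Ifng, 0.02 for Ifngr1, -0.36 for Ifngr2, 0.10 for Fas, 0.10 for Bcl2 (adjusted p = 1 each) and -8.86 for Fasl (adjusted p = 0.76). The count depends on the error assumed, since 10 genes passed with the upper bound of the standard error. With scaling by library size 292 genes passed, 24 higher and 268 lower, or 8.22% higher against 47.8%, and Lrrc47 and E2f2 did not.

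Against anti-PD-1 DANA alone, the combination again had lower mitochondrial transcripts, with mt-Atp8 at -3.10 ± 0.38 (adjusted p = 2.22e-12) and mt-Cytb at -2.35 ± 0.33 (adjusted p = 1.09e-08). E2f2 was higher at 6.96 ± 1.59 (adjusted p = 0.0135), as was Rad54l, a gene of homologous recombination repair, at 8.53 ± 1.88 (adjusted p = 0.00839), while Lmnb2, a nuclear lamin, was lower at -7.08 ± 1.71 (adjusted p = 0.0271). In all 80 genes passed, 35 higher and 45 lower in the combination. The mitochondrially encoded list was the only one of 26 to pass (adjusted p = 2.30e-31, or 4.67e-22 with a correlation of 0.05), with 7 of 13 members called lower, 11 lower when adjusted over the list alone and a median of -1.31. With ranks the mitochondrially encoded list had an adjusted p of 1.66e-06. The 25 uncalled lists had adjusted p from 0.336 to 0.981. Of these, interferon-stimulated genes and the T cell receptor list were lower on library size scaling (adjusted p = 0.00938 and 0.00487). Neither passed with the level trend removed (adjusted p = 0.269 and 0.606). Other genes higher in the combination were Myo1h (13.58), Txnl4b (8.79), Sergef (8.67), Col23a1 (8.61), a transmembrane collagen, Zbtb22 (8.60), Tmem107 (8.58) and Pomt1 (8.57), a protein mannosyltransferase. Lower were Dse (-8.58), an epimerase of dermatan sulfate, Hsbp1 (-7.38), Thap11 (-7.14), Ccdc86 (-7.12), Kdm4b (-7.06), a histone demethylase, Reck (-6.98) and Ppp2r1b (-6.98), a phosphatase scaffold subunit. The genes named in advance differed by 0.68 for Pdcd1, -0.05 for Ctla4, 2.14 for Ifng, 0.83 for Ifngr1, -0.82 for Ifngr2, 0.70 for Fas, 0.24 for Bcl2 and -7.33 for Fasl (adjusted p = 1 each). With the upper bound of the standard error 6 genes passed. On library size scaling 227 genes passed, 30 higher and 197 lower, or 13.2% higher against 43.8%.

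Departure from additivity was the combination minus the sum of both single treatments, on the log2 scale. Lag3 lay above the sum at 9.33 ± 2.04 (adjusted p = 0.00259), as did Klf2 at 4.13 ± 0.97 (adjusted p = 0.00666), a call lost on library size scaling (2.47). Against isotype Lag3 was called lower after anti-CTLA-4 (-8.20) and was not called with the combination. Its place above the sum therefore does not show a rise over isotype. Prf1 lay below the sum at -7.30 ± 1.89 (adjusted p = 0.0201), as did Il15ra at -12.58 ± 2.62 (adjusted p = 0.00131), Fadd, an adaptor of death receptors, at -10.39 ± 2.59 (adjusted p = 0.0137), and mt-Atp8 at -2.99 ± 0.53 (adjusted p = 5.68e-05). Prf1 rose in all 3 comparisons (5.57, 7.07 and 5.34), so its place below the sum follows from adding 2 rises over the same isotype arm. A gene scarce in isotype and higher after both antibodies meets the sum only if its rises multiply. A place below the sum therefore does not show that the antibodies counteract each other. In this contrast 435 genes passed, 142 above and 293 below the sum. Mitochondrially encoded genes (adjusted p = 5.20e-06) had 4 of 13 members below the sum, mt-Nd4l, mt-Nd5, mt-Cytb and mt-Atp8, and 7 when adjusted over the list alone. They also passed with a correlation of 0.05 (adjusted p = 0.000352) and with ranks (adjusted p = 0.00299). B cell markers (adjusted p = 0.0409, or 0.222 with a correlation of 0.05) had 3 of 23 below the sum, Fcrla, Spib and Pou2af1, and 4 when adjusted over the list alone. Naive and memory genes (adjusted p = 0.026), nuclear oxidative phosphorylation genes (adjusted p = 0.00655) and immediate early genes (adjusted p = 0.0206) lay above the sum. These 3 did not pass with a correlation of 0.05 (adjusted p = 0.199 each) or with the level trend removed (adjusted p = 0.798, 0.871 and 0.798). Among random lists matched on level their medians lay at percentile 19.8, 83.2 and 85.1, so the naive and memory median of 0.57 was below the 0.98 of genes of its level. The 21 uncalled lists had adjusted p from 0.0565 to 0.863.

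Genes with strongly negative fold changes after both antibodies, called or not, lay above a sum lower than reads could reach, so part of their departure comes from the subtraction: Myo1h (27.06), Pcnx4 (17.34), Mlf1 (16.53), Zscan22 (16.49), B3gnt9 (16.07), Hipk4 (15.27), Lrrc8b (14.93), a volume-regulated channel subunit, Glyctk (14.77) and E2f2 (14.46). The rest depends on the combination's own level. Myo1h was called higher in the combination than after anti-CTLA-4 (13.67) and anti-PD-1 DANA (13.58). So was E2f2 (6.13 and 6.96), the first a call lost on library size scaling. Other genes above the sum were Hspa1a (8.75), Uqcrh (2.50), a complex III subunit, and the chaperone gene Hsp90ab1 (1.90). Below the sum were Coq8a (-18.24), Hint3 (-16.53), Cars (-15.55), a cysteinyl-tRNA synthetase, the tetraspanin gene Cd81 (-15.53), Fcrla (-15.50), Nudt2 (-15.41), Syde1 (-15.14), Grhpr (-14.90), Dnajb9 (-14.25), Pou2af1 (-14.00), Rgs1 (-11.58), Spib (-10.37), Pfkl (-9.03) and mt-Cytb (-2.24). For those that rose after both antibodies, such as Rgs1, the limit given for Prf1 holds. For the genes named in advance the departures were 2.06 for Pdcd1, 2.14 for Ctla4, 4.05 for Ifng, -0.92 for Ifngr1, 2.05 for Ifngr2, -0.23 for Fas (adjusted p = 1 each), 1.66 for Bcl2 (adjusted p = 0.404) and -15.64 for Fasl (adjusted p = 0.0718), whose reads came mostly from 1 library in each antibody arm. With the upper bound of the standard error 70 genes passed. With scaling by library size 841 genes passed, 48 above and 793 below, or 5.71% above against 32.6%, and Mlf1, Klf2, Uqcrh, Hsp90ab1 and Hspa1a did not.

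The 3 comparisons against isotype shared many called genes, among them Prf1, Tbx21, Gadd45b and Casp6, called higher in each, and Birc6 and Fcgr3, called lower in each. Fcgr3 rests on 1 isotype library common to the 3, Tbx21 on 1 library in the combination, and on library size scaling Birc6 is no longer called after either antibody alone nor Fcgr3 after anti-CTLA-4. Called higher in all 3 of the authors' deposited tables were 146 genes, and called lower 55. Anti-CTLA-4 and anti-PD-1 DANA shared 262 genes called higher and 95 called lower. Anti-CTLA-4 and the combination shared 216 higher and 116 lower, and anti-PD-1 DANA and the combination 216 higher and 115 lower. All 3 use the same isotype libraries, so no overlap expected by chance is given. Opposite calls numbered 0, 2 and 2. Across 17831 genes, which are not independent replicates, Pearson's r of the fold changes was 0.58 for the antibodies alone, 0.52 for anti-CTLA-4 with the combination and 0.55 for anti-PD-1 DANA with the combination, where unchanged groups simulated against shared controls gave 0.49 each. The covariance was 6.71, 5.89 and 6.23 against simulated values of 2.48, 2.59 and 2.50. Among the 8914 genes above the median level r was 0.81, 0.66 and 0.70, against 0.50 each in the simulation. The 3 isotype libraries cannot be split with 2 in each part, so part of the excess may come from the shared controls.

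T cell receptor segments give a view of the clones in each pool. With the combination 5 of 23 tested Trbv segments were called lower, Trbv14 (-8.39), Trbv15 (-7.64), Trbv19 (-7.43), Trbv26 (-9.03) and Trbv31 (-6.48) in the authors' deposited table, while 0 of 23 were called after either antibody alone. None of these 5 passed in the combination against anti-CTLA-4 (adjusted p from 0.0549 to 1) or against anti-PD-1 DANA (adjusted p from 0.0649 to 0.86), and all 5, as well as Trav8-2, rested on 1 isotype library for 80% or more of their reads. Of 111 Trav segments, 2 were called higher and 9 lower with the combination, 3 higher and 1 lower after anti-CTLA-4, and 2 higher and 2 lower after anti-PD-1 DANA in the authors' deposited table. Trav8-2 was called lower in all 3 comparisons (-7.84, -11.11 and -9.14), and Trav12-2 higher after anti-CTLA-4 (6.52) and anti-PD-1 DANA (7.43) in the authors' deposited table. Trbv12-1 was lower in the combination than after anti-CTLA-4 at -6.92 ± 1.61 (adjusted p = 0.0118) and than after anti-PD-1 DANA at -7.13 ± 1.61 (adjusted p = 0.0121). None of 50 Traj or 13 Trbj segments was called in any comparison. Of the 16 segments called with the combination, 2 were left without those found to rest on 1 library, and near-identical copies within the Trav family can share reads. Segments were named after their values were seen.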

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

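The differences between treatments were planned contrasts computed with a rule for the error that was chosen after the data had been seen, the search for untested genes was also chosen then, and all tests of explanations in this part were chosen after the results were seen.

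The effects of the combination and of anti-CTLA-4 against isotype differed, by a test of the difference itself, in 161 genes, but in 10 with the upper bound of the error, and on library size scaling in 292, 24 higher and 268 lower. Higher in the combination were Myo1h (log2 difference 13.67), Lrrc47 (10.62), Gatb (8.91), Sp6 (8.84), Clcn5 (8.83), Tmem37 (8.74), Chaf1a (8.43), Birc5 (8.37), Hspa1a (7.40), Lag3 (7.24) and E2f2 (6.13). Lower were Spib (-8.12), Pskh1 (-7.89), Pramef8 (-7.87), Dhx32 (-7.70), Plbd2 (-7.65), Tmem9 (-7.63), Ccdc86 (-7.61), Ext2 (-7.52), Pfkl (-6.63), mt-Atp8 (-3.01) and mt-Cytb (-2.49). As lists, mitochondrially encoded genes (adjusted p = 2.61e-21), B cell markers (adjusted p = 2.10e-06) and CD4 and regulatory T cell markers (adjusted p = 0.0391) were lower and nuclear oxidative phosphorylation genes higher (adjusted p = 0.0307). The last 2, with 0 of 12 and 0 of 41 members called, did not pass with a correlation of 0.05 (adjusted p = 0.156 and 0.241), with the level trend removed (adjusted p = 0.0913 and 0.469) or on library size scaling (adjusted p = 0.0617 and 0.679).

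The effects of the combination and of anti-PD-1 DANA differed in 80 genes, but in 6 with the upper bound of the error, and on library size scaling in 227, 30 higher and 197 lower. Higher in the combination were Myo1h (13.58), Txnl4b (8.79), Sergef (8.67), Col23a1 (8.61), Zbtb22 (8.60), Tmem107 (8.58), Pomt1 (8.57), Rad54l (8.53) and E2f2 (6.96). Lower were Dse (-8.58), Hsbp1 (-7.38), Thap11 (-7.14), Ccdc86 (-7.12), Lmnb2 (-7.08), Kdm4b (-7.06), Reck (-6.98), Ppp2r1b (-6.98), mt-Atp8 (-3.10) and mt-Cytb (-2.35). Mitochondrially encoded genes were lower as a list (adjusted p = 2.30e-31).

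Among genes the authors did not test, 3 had a mean of 100 RPKM or more in the combination and at least 2 times the isotype mean, as the authors' means in their deposited tables: Mir6236 (866.8 against 317.1 RPKM), Gm12896 (238.6 against 78.7 RPKM) and Gm24407 (122.4 against 35.3 RPKM). No value per library exists for them here, so the difference was not tested.

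Mitochondrially encoded genes were lower with the combination by a median log2 fold change of -1.38, and in the same arm Lars2 (2.04) and the uncalled Rn18s-rs5 (1.16) in the authors' deposited table and the untested Mir6236 (866.8 against 317.1 RPKM) lay higher. The authors' composition scaling is argued against as the cause, since the median on library size scaling was -1.27. A few transcripts taking reads would lower all abundant genes, but the 239 nuclear genes of 100 RPKM or more had a median of 0.10 (quartiles -0.57 and 0.72). By library size, genes of 20 to 100 RPKM centred at -0.79 in this arm, against -0.16 after anti-CTLA-4 and -0.21 after anti-PD-1 DANA. A loss of reads to a few transcripts is therefore argued against only for the 239 genes and is not excluded. An even loss of mitochondrial transcripts is argued against by a spread of the 13 fold changes, from -3.13 to 0.74, beyond their errors, with a heterogeneity over degrees of freedom of 7.58 where errors alone give about 1. An uneven effect of the treatment, or of the single pool of cells and the composition of its RNA, may account for the pattern, and these cannot be told apart with 1 pool per arm.

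B cell markers were higher after anti-CTLA-4, with 5 members called at 6.03 to 7.89. A larger share of B cells as the whole cause would bring all abundant B cell transcripts, but the 11 members of 20 RPKM or more had a median of 0.41, Cd74 at 0.32, Ighm at -0.12 and H2-Ab1 at 0.41. Independent loss of scarce transcripts in isotype is argued against by the list median, at percentile 99.92 of random lists matched on level, and reads of 1 library by the largest share, 47.3%, among the 2 called members with recovered reads. The 11 abundant members still lay 1.01 log2 units above the median of the T cell receptor list, so a smaller contribution of B cells could remain. The treatment itself was not tested apart from its pool.

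Of genes called lower than isotype, reads per library were recovered for 114 of 266, 98 of 235 and 232 of 640, those with few reads, and 102, 91 and 196 of these rested on 1 isotype library. One aberrant isotype library is argued against, since none held more than 39.6% of them in any comparison. Scarce transcripts reaching only some of the split aliquots may account for it, since at least 68.9% of uncalled genes of the same level also rested on 1 isotype library. An effect of the treatment that lowers these genes cannot be told apart from its pool, as there was 1 pool of mice per arm.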

How the results depend on the processing

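Apart from the similarity of genes above the median level, which was planned, all tests in this part were chosen after the results were seen. Other tests written down before the data were examined were not run because the tables hold no values per library: other normalizations, tests and count filters, fits of only the compared groups, replicate and sample-sheet blocks, leaving out each library, pseudocounts, the rotation list test, the estimated correlation of camera, and segment counts per library. No paired analysis was possible because the tables carry no value per replicate. Other splits of the libraries could not be run for the same reason, and 3 libraries against 3 are too few for a share under 0.05.

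Counts are given in the order anti-CTLA-4, anti-PD-1 DANA and combination against isotype, combination against anti-CTLA-4, combination against anti-PD-1 DANA, departure from additivity, where the main counts were 754, 669, 1343, 161, 80 and 435 genes. Adjusting over the tested genes gave 1616, 1596, 2238, 353, 224 and 846, since fewer genes enter the adjustment, and Bonferroni adjustment, stricter by construction, gave 27, 34, 74, 34, 14 and 50. Library size scaling gave 1367, 1221, 1359, 292, 227 and 841. With a larger mean of 5 RPKM or more the counts were 822, 731, 1175, 424, 311 and 637, and those against isotype and for additivity stayed within 1.5 times the main count. The share higher for the combination against isotype fell to 38.8% there, and the cause was not tested. The upper bound of the error gave 10, 6 and 70 for the last 3. Without genes found to rest on 1 library the first 3 were 623, 561 and 971, most of which could not be assessed for it.

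Of 26 lists, 10, 3, 4, 4, 1 and 5 passed in the same order. A correlation of 0.05, which widens the error by construction, gave 0, 0, 1, 2, 1 and 1, ranks gave 10, 6, 6, 3, 1 and 3, library size scaling 2, 2, 3, 3, 3 and 2, and removal of the level trend 2, 1, 2, 2, 1 and 2. Mitochondrially encoded genes were lower in the combination in each of these settings, in all 4 comparisons that involve it. B cell markers were higher after anti-CTLA-4 in each setting but the correlation of 0.05 (adjusted p from 0.000185 to 0.0867).

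Receptor segments called against isotype, 4, 4 and 16, became 10, 13 and 25 over tested genes, 0, 0 and 0 with Bonferroni adjustment, 14, 17 and 28 at 5 RPKM or more, 8, 10 and 16 on library size scaling, and 3, 2 and 2 without those mostly in 1 library. Pearson's r among genes above the median level was 0.81 for the antibodies alone, 0.66 for anti-CTLA-4 with the combination and 0.70 for anti-PD-1 DANA with the combination, against 0.50 each in unchanged groups simulated with shared controls. For the counts of genes, lists and segments that differed with library size scaling, the 5 RPKM minimum, ranks, removal of the level trend or removal of genes mostly in 1 library, the cause was not tested.

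Of 254 results for named genes, library size scaling left 224 with the same direction and call, made 20 weaker and 2 stronger (Fasl after anti-CTLA-4, where all its reads lay in 1 library, and for additivity), and turned 8 that were not called, by construction through the shift of all genes: Ctla4 after anti-PD-1 DANA (0.50), Pdcd1 (-0.24), Ifngr1 (-0.82), Fas (-0.74) and Bcl2 (-0.74) in the combination against anti-CTLA-4, Pdcd1 (-0.032) and Bcl2 (-0.47) in the combination against anti-PD-1 DANA, and Fas, combination against anti-PD-1 DANA (-0.0109). Calls lost there include Fcgr3, Ifit3, Birc6, Lat and Ptprc after anti-CTLA-4, Pklr, Birc6, Dusp2, Hsph1 and Ccr6 after anti-PD-1 DANA, Dusp2 and Ccr8 with the combination, Lrrc47 and E2f2 in the combination against anti-CTLA-4, and Mlf1, Klf2, Uqcrh, Hsp90ab1 and Hspa1a for additivity. Bonferroni adjustment made 171 weaker and the upper bound of the error 60, and no other direction turned. No test here varied depth. Among 1248 genes with a standard error under 1, 36, 26 and 70 were called against isotype, 3, 2 and 10 of them higher and 33, 24 and 60 lower, against more higher than lower in each main count. Called genes had a median larger mean of 6.03, 6.57 and 6.04 RPKM.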

Other observations

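The genes in this part were chosen after their values were seen, and no explanation was tested for them.

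The fold changes of Lars2 and Rn18s-rs5, abundant RNAs outside the fixed lists, went in different directions between treatments. Lars2, which encodes the mitochondrial leucyl-tRNA synthetase, was called lower after anti-CTLA-4 (log2 fold change -2.46 ± 0.33, adjusted p = 1.99e-09) and anti-PD-1 DANA (-1.49 ± 0.33, adjusted p = 0.0034) and higher with the combination (2.04 ± 0.33, adjusted p = 1.79e-06) in the authors' deposited table. Rn18s-rs5, a locus related to 18S ribosomal RNA, followed the same order at -2.56 (adjusted p = 2.48e-06), -1.46 (adjusted p = 0.0274) and 1.16, the last not called (adjusted p = 0.0946), in the authors' deposited table. The difference between the combination and anti-CTLA-4 was 4.51 for Lars2 (adjusted p = 6.90e-39) and 3.73 for Rn18s-rs5 (adjusted p = 1.98e-16). Malat1, an abundant nuclear RNA, was at -1.19 (adjusted p = 0.0287), -1.45 (adjusted p = 0.00515) and -0.95 (adjusted p = 0.102) in the authors' deposited table. Cd8a, on which the cells were sorted, was at -0.13, 0.09 and -0.12 (adjusted p = 1 each), and Trac, the constant segment of the receptor alpha chain, at -0.77, -0.51 and -0.80 (adjusted p = 0.903, 1 and 0.814) in the authors' deposited table.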
